A study of Sus scrofa with 8 samples.

How the data were processed

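Transcript levels were measured with oligonucleotide arrays in T cells of 2 Large White x Landrace sows. Per the labels' protocols, mononuclear cells of colostrum and of blood were stained for CD3, CD4 and CD8, and CD3-positive cells were sorted into a CD8-positive, CD4-negative population (CD8 single positive) and a population positive for both CD4 and CD8 (double positive). This gives 4 groups of 2 samples, 1 from each sow. The titles of the double positive samples carry the words of both populations, and the group was taken from the series' design text and the sort. Per the labels, total RNA was purified, 10 ng was amplified as cDNA with the Ovation PicoSL WTA system, and the cDNA was labelled with Alexa Fluor 3 for every colostrum sample and Alexa Fluor 5 for every blood sample. No dye was swapped, so the dye and the source of the cells cannot be told apart in a comparison of colostrum with blood. A dye effect that is the same in both populations cancels in the difference of those comparisons and does not enter the comparisons of populations within colostrum or within blood.

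The deposited file of each sample holds the probe name and 1 whole-number intensity for each of 45220 spots, with no header. The values behave as intensities from which a background had been subtracted, since some lie below 0. The scanner, the image software and the background method are not given in the sources used here. The authors' deposited series matrix holds log2 values of 43603 probes. Its 8 columns share 1 distribution, with a median of 6.32, and 1245 values are empty in each. These log2 values were rebuilt by quantile normalization of the deposited intensities before the log: 79.0% of 338770 values lay within 0.01 and 99.3% within 0.1 of the matrix. The matrix was used as an alternative.

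Control spots were left out of the tests, and the spots of 50 probes printed more than once were averaged. The 8 channels were quantile normalized over the 43603 probes, a floor was set at 40.6 intensity units (5.34 on the log2 scale, the mean over the channels of the normalized median of the 153 negative-control spots), and log2 was taken. The floor was chosen after the unit of the files was seen. Values at the floor have no order, and 11.2% of the tested values lay there. The platform annotation gives 10278 probes 1 gene symbol, gives 0 probes several symbols and leaves 33325 probes unnamed here. Unversioned RefSeq accessions matched for 6051 probes against the names of the Sscrofa11.1 annotation, which changed the symbol of 443, and the older symbol was kept otherwise. Probes were kept when their mean over the 8 samples was above the 30th percentile, and each gene was represented by its brightest probe, which gave 3773 genes of 4560 with a symbol. Members of families of near-identical genes, such as HSP70.2, IFITM1, the granzymes and the CCL3 and CCL4 chemokines, can share signal between probes.

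The number of arrays limits the precision. Files without detection calls were given one from the negative controls: a probe counted as above background in a channel when it exceeded their 95th percentile, which 31.1% to 34.7% of the probes did in the colostrum channels and 28.9% to 36.1% in the blood channels. A probe not well above background on either array of a group has only a bound there. The bound is that of the tested probe, and other probes of the gene that were above background there are given beside it or the difference is given instead. Over the 4 comparisons of 2 groups, the other probes of 52 genes put through the alternatives gave 184 differences with the probe above background on both arrays of a group compared; 169 had the sign of the tested probe, 15 the opposite sign, and 121 had that sign and at least 0.5 of its size. This comparison was added after the data were seen. Its fold is then given as "at least", from the mean of the brighter group against the mean of, for each array of the dimmer group, the higher of the detection threshold and the probe's own value.

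limma (version 3.58.1, R 4.3.3) was fitted to the 8 samples with 4 group means and no block for the sow, with moderated variances (4 residual and 5.39 prior degrees of freedom), and Benjamini-Hochberg adjusted p-values under 0.05 were called. The comparisons were colostrum against blood in each population, the difference between these, and double positive against CD8 single positive cells within colostrum and within blood. Of 25 gene lists written down before the data were examined, 24 had at least 2 measured genes and were tested with limma's camera at its preset correlation of 0.01 and again with an estimated correlation. With an estimated correlation, camera refers its statistic to the 4 residual degrees of freedom, which makes a call harder. A count given as adjusted over the list alone uses only the p-values of that list. In 20 simulated data sets of 3773 genes with the spread of these samples and 200 changed genes, the comparison in CD8 single positive cells recovered 0.9% of the genes changed by 1, 26.9% of those changed by 2, 57.5% of those changed by 3 and 82.3% of those changed by 4 on the log2 scale, and 3.84% of the calls were false. In separate simulations without the 200 changed genes, camera found a list of 8 genes shifted by 1 in 16 of 20 data sets. It called 2 of 460 unshifted lists. The simulated genes were independent, whereas the estimated correlation of the heat shock list was 0.608. These simulations therefore do not give the rate of false calls for lists of correlated genes.

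Genes were named by a rule fixed before the data were examined: in each comparison of colostrum with blood the 8 largest rises and falls past the threshold, made up to 8, as values and not as calls, by the largest differences with the same sign and at least 2-fold in both sows; the 7 genes of the sort; from each list up to 4 members that passed or, where none did, at most 1 as a value. Not every such value is printed. Genes named by their p adjusted over a list alone were chosen after their values were seen. The samples are paired by sow, per the labels' source names. Deviations from the group means of the same sow correlated at 0.28 between colostrum and blood CD8 single positive cells and at 0.22 between colostrum and blood double positive cells, and at -0.02 to 0.08 between the other 4 pairs of groups. Raw intensities of the same sow and population also correlated more closely (Spearman 0.63 to 0.67 over probes) than those of other samples (0.49 to 0.59), as 2 channels of a shared array would; the labels do not say which samples shared an array. Alternatives covered the scaling, the background, the filter, the pairing, the choice of probes and leaving out each sample.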

Results

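The data are probe intensities of 8 samples of sorted porcine T cells: CD8 single positive and double positive cells from colostrum, the first milk, and from blood, each from 2 sows. Mature CD4 and CD8 double positive T cells are a normal population of the pig. The series was designed to compare colostral with blood T cells within each population. The median probe intensity was 118 to 133 units in the colostrum channels and 27 to 34 in the blood channels before normalization, with medians of the negative-control spots of 68 to 81 and 1 to 8. From 7 to 22 probes in a colostrum channel and 28 to 60 in a blood channel were saturated. All levels below are normalized log2 intensities, and differences are log2 values with the standard error of the limma fit.

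The genes of the sort were read first, as a check of the labels. CD8B, the beta chain of CD8, was at 9.71 ± 0.18 (SD, n = 2) in colostrum and 8.32 ± 0.91 in blood CD8 single positive cells, and its probe was not well above background in double positive cells of either source. CD4 was at 9.07 ± 0.93 (SD, n = 2) in blood double positive cells and not well above background in blood CD8 single positive cells, at least 4.40-fold higher. In colostrum, CD4 was at 7.06 ± 0.09 in double positive cells, close to the detection threshold, and at 6.14 ± 1.13 in CD8 single positive cells, where 1 of 2 arrays measured it. The CD3 chains CD3D and CD3E were bright in all groups, with means between 11.63 and 12.08.

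**Figure D1:**
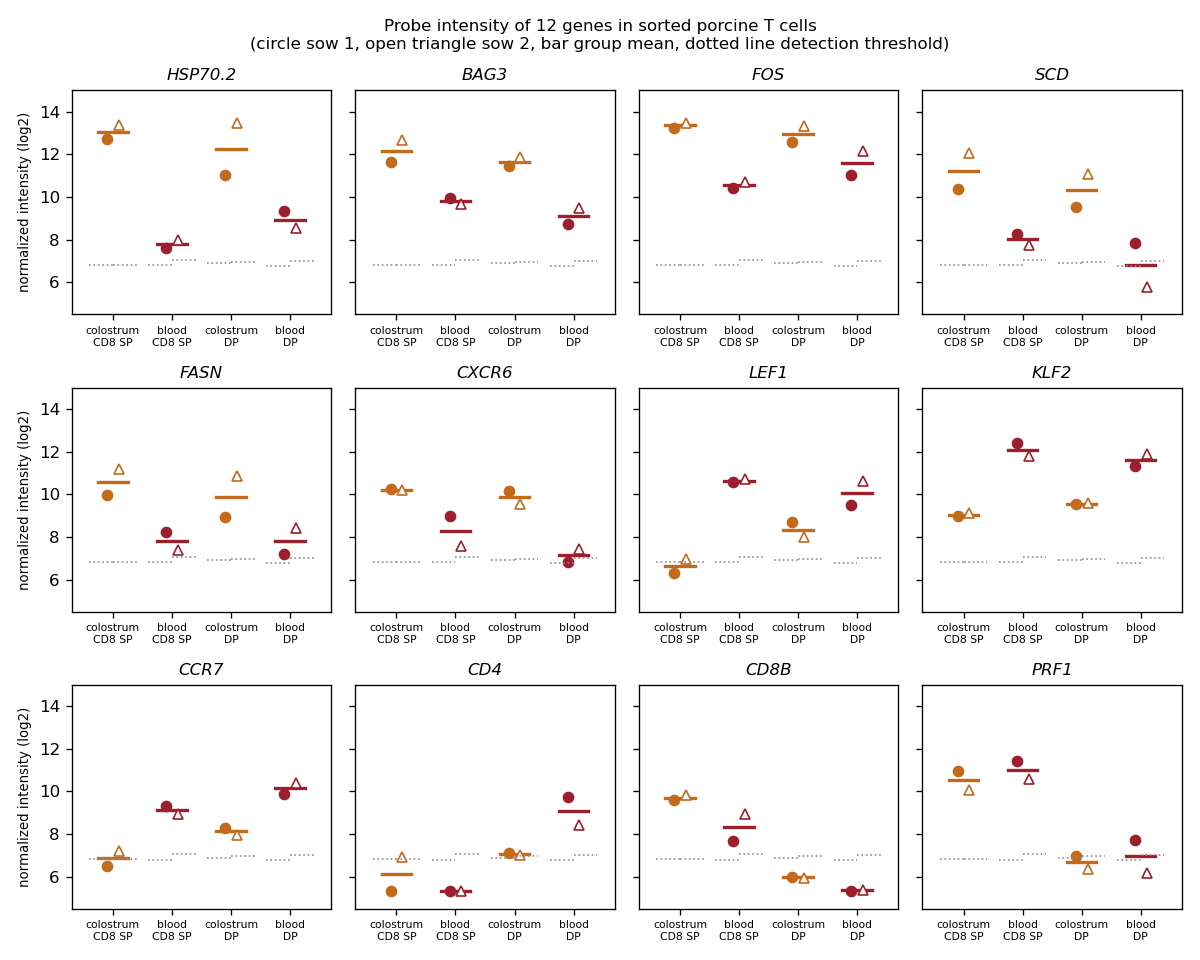
Normalized log2 intensity (vertical axis) of 12 genes in the 4 groups (horizontal axis). Circles are sow 1, open triangles sow 2, bars group means and dotted lines each channel's detection threshold; HSP70.2 means were 13.05 and 12.25 in the colostrum groups against 7.80 and 8.94 in blood, and KLF2 means were 9.04 and 9.56 against 12.09 and 11.61.

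In CD8 single positive cells, the lists with the largest median differences between colostrum and blood that were called at camera's preset correlation were heat shock genes, brighter in colostrum, and genes of naive and lymph node homing T cells, dimmer in colostrum. Neither was called with an estimated correlation (adjusted p = 0.321 and 0.283), and under 75th percentile scaling the heat shock median fell to 0.27 and was not called (0.494). HSP70.2, an inducible HSP70 chaperone, had the largest difference, 5.26 ± 0.76 (SE, n = 2 per group), with means of 13.05 ± 0.47 and 7.80 ± 0.25 (SD). LEF1, a transcription factor of naive T cells, was at 6.65 ± 0.46 in colostrum, where 1 of 2 arrays measured it, and at 10.64 ± 0.12 in blood, a difference of -3.99 ± 0.56. Other probes of LEF1 differed by less, -1.03 and -2.10. KLF2, a transcription factor of T cell quiescence and trafficking, differed by -3.05 ± 0.48, and by -1.59 with another probe. CCR7, the receptor for entry into lymph nodes, differed by -2.25 ± 0.50, with 1 of 2 colostrum arrays measuring it. Each of these differences had the same sign in both sows. None passed limma's test after adjustment over 3773 genes: the smallest adjusted p, 0.109, was shared by LEF1 and HSP70.2.

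The list of heat shock genes was shifted up, with a median of 1.72 over 8 genes (1.47 in sow 1 and 2.13 in sow 2) and 7 of 8 higher in colostrum (camera adjusted p = 1.42e-08; adjusted p = 0.321 with an estimated correlation). Adjusted over the list alone, 6 of 8 passed, among them the chaperone genes HSPH1 (2.37), HSP90AA1 (1.62), HSPB1 (1.82) and DNAJB1 (1.45, but -0.09 under 75th percentile scaling) and the HSP70 partner BAG3 (2.34). The naive and lymph node homing list was shifted down, with a median of -1.80 and all 6 measured genes lower (camera adjusted p = 6.8e-07; adjusted p = 0.283 with an estimated correlation). Adjusted over that list alone, 4 of 6 passed: LEF1, KLF2, CCR7 and the interleukin 7 receptor gene IL7R (-1.29). Cholesterol and lipid genes had a median of 0.67 (0.06 under 75th percentile scaling, not called), with 9 of 10 higher (camera adjusted p = 0.000464; adjusted p = 0.283 with an estimated correlation). In that list the fatty acid synthase FASN (2.78 ± 0.77), the desaturase SCD (3.19 ± 0.85), the squalene epoxidase SQLE (at least 3.09-fold higher) and LPIN1 (1.39 ± 0.47) passed adjusted over the list alone. FASN differed by 1.74 in sow 1 and 3.82 in sow 2, and SCD by 2.07 and 4.32. The probes of SQLE disagree: the tested probe was not well above background in blood, and another that was above it on both blood arrays differed by -0.08. Another FASN probe, above background on both colostrum arrays, differed by 0.04, and the other LPIN1 probes differed by 1.31, 1.02, 0.43, 0.18 and -0.01. Immediate early genes had a median of 0.73 over 8 genes, but of -0.68 under 75th percentile scaling (camera adjusted p = 0.0053; adjusted p = 0.321 with an estimated correlation and 0.114 without colostrum replicate 2). FOS (2.78 ± 0.54) and EGR2 (1.83 ± 0.55; 2.79 in sow 1 and 0.87 in sow 2; measured on 1 of 2 blood arrays) passed adjusted over the list alone. Type 1 genes had a median of 0.76 over 9 genes (0.29 under 75th percentile scaling, not called; camera adjusted p = 0.0331; adjusted p = 0.321 with an estimated correlation), or 0.49 with genes at their bound. IFNG, the interferon gamma gene, had the largest difference among them, 2.15 ± 0.67 with 1 of 2 blood arrays above background, and did not pass. In the other lists GZMA and the kinase gene PDK1 (-2.07 ± 0.58, with -1.001 in sow 1 and -3.147 in sow 2) passed adjusted over their list alone. The nucleotidase gene ENTPD1 (at least 1.26-fold higher, its tested probe not well above background in blood) is on 2 lists. It passed over inhibitory receptors alone, with 2 of 9 genes measured, and not over regulatory genes, with 5 of 8 measured. ENTPD1 took the opposite sign under 75th percentile scaling (-2.20), under cyclic loess (-3.05) and with the mean of its probes (-0.25), and the 1 probe of it above background on both blood arrays differed by -1.71.

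The other large differences of the same sign in both sows are values, not calls. Higher in colostrum were SHAS2, named for a hyaluronan synthase (2.53 ± 0.69), and INTS6, a subunit of the Integrator complex (2.91 ± 0.69), which 1 of 2 blood arrays measured and whose other probes differed by 0.67, 0.52 and -0.35. The granzyme gene GZMA was at least 3.06-fold higher and RASA2, a Ras GTPase activator, at least 3.29-fold higher, since their tested probes were not well above background in blood. GZMA differed by 3.68 in sow 1 and 1.37 in sow 2. Lower in colostrum were IFITM1, an interferon-induced membrane protein (-2.57 ± 0.56), the small GTPase gene RAP2A (-2.22 ± 0.60), TDRD7 (-2.66 ± 1.13) and MAGED1 (-2.39 ± 0.55), the last 2 measured on 1 of 2 colostrum arrays. TDRD7 differed by -3.76 in sow 1 and -1.57 in sow 2. Another probe of TDRD7 differed by only -0.615, and another of MAGED1 by -2.48. The efflux transporter gene ABCG2 was at least 1.86-fold lower by its tested probe, while other probes of it differed by -1.95, -0.29 and 0.87. None of the sort genes passed: CD3D differed by -0.10 ± 0.51, CD3E by 0.02 ± 0.49, CD3G by -0.38 ± 0.79, and CD247 by -0.45 ± 0.64, each of these with opposite signs in the sows. CD8A differed by -0.71 ± 0.52 and CD8B by 1.40 ± 0.53, higher in both sows (1.91 and 0.89), while a second CD8B probe differed by 0.35.

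Among markers of other cells, the milk protein gene CSN1S1 was at 9.37 ± 2.84 in colostrum and 7.09 ± 2.14 in blood CD8 single positive cells, with both high values in sow 2. Of its other probes, the only one above background on both arrays of a group differed by -1.60. The monocyte gene LYZ was at least 1.69-fold lower in colostrum, and the platelet gene GP9 differed by -1.17 ± 0.48. The neutrophil gene S100A12, measured on 1 of 2 blood arrays, was at least 2.12-fold lower, but this rests on sow 2 (-0.08 in sow 1 and -2.80 in sow 2). FCER1G, found in NK and gamma delta T cells, differed by 1.87 ± 0.72 and was measured on 1 of 2 blood arrays, as CSN1S1 was. None of the 5 lists of other cell types passed in this comparison, the lowest adjusted p being 0.105 for red cells and platelets.

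limma called 0 genes higher and 0 lower in colostrum CD8 single positive cells, against 288 genes at an unadjusted p under 0.05, where 189 would be expected by chance. With the sow and population pair as a random block, 1 gene was called higher, HSP70.2, and 1 lower, LEF1 (adjusted p = 0.0489 for both). Normexp background correction called HSP70.2 higher and LEF1 and KLF2 lower (adjusted p = 0.0119 for each), and leaving out either colostrum double positive replicate called HSP70.2 (0.0421). By size alone, 126 genes were at least 2-fold higher and 137 at least 2-fold lower in both sows, while 98 moved at least 2-fold in opposite directions. Scaling each channel by its 75th percentile ended the call of the heat shock (median 0.27, adjusted p = 0.494), lipid (0.06, 0.494) and type 1 lists (0.29, 0.58) and turned the median of the immediate early list to -0.68 (0.782). The naive list kept its call under it, with a median of -2.36. Without colostrum replicate 2, the type 1 (adjusted p = 0.335) and immediate early lists (0.114) were not called, nor was the type 1 list without blood replicate 1 (0.0782) or 2 (0.0909), with cyclic loess (0.0545) or with normexp (0.0535).

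**Figure D2:**
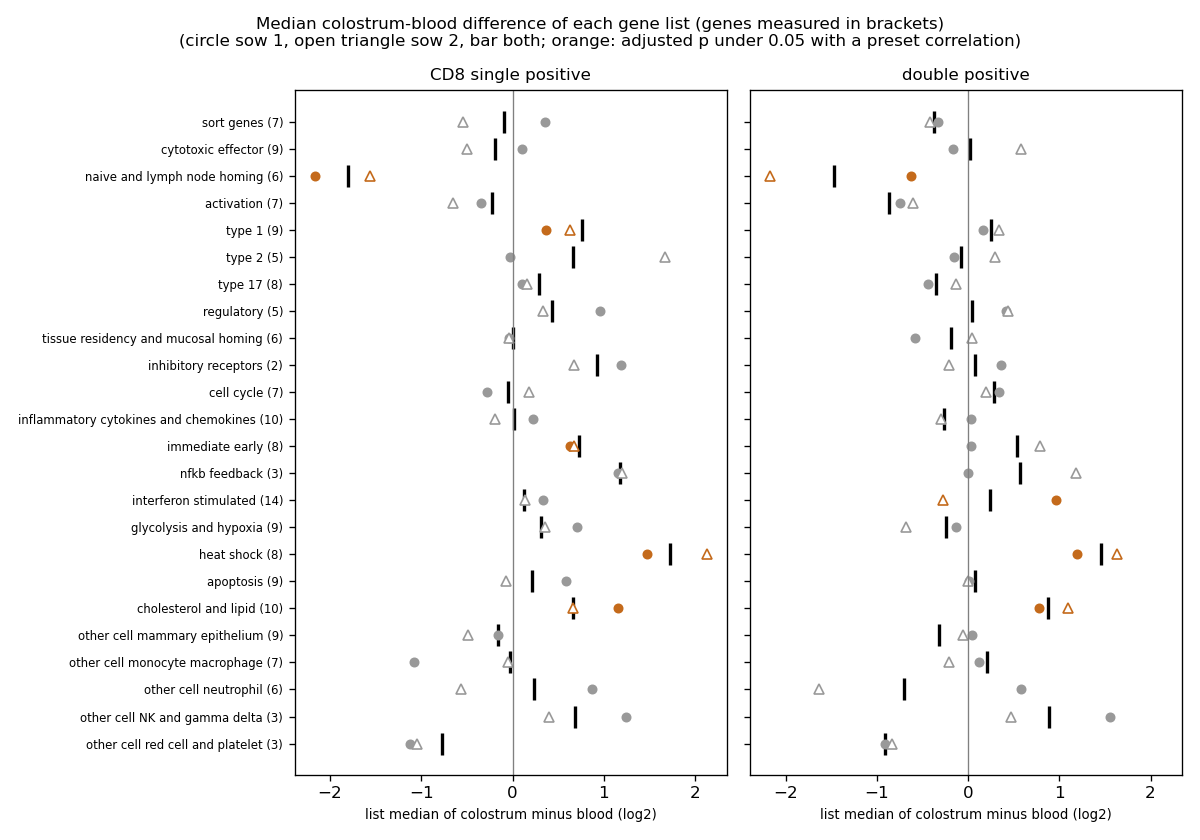
Median log2 difference of colostrum minus blood (horizontal axis) for 24 gene lists (vertical axis) in CD8 single positive and double positive cells. Circles are sow 1, open triangles sow 2, bars the median of both, and orange marks lists with a camera adjusted p under 0.05 at the preset correlation; the heat shock medians were 1.72 and 1.46 (0.27 and -0.24 under 75th percentile scaling) and the immediate early median in CD8 single positive cells 0.73 (-0.68 under it), and the naive and lymph node homing medians -1.80 and -1.47.

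In double positive cells, the heat shock and lipid lists were called brighter in colostrum and the naive and lymph node homing list dimmer at camera's preset correlation, and none of these with an estimated correlation (adjusted p = 0.538, 0.279 and 0.538). Under 75th percentile scaling the heat shock median turned to -0.24 and the lipid median fell to 0.24, and neither was called. HSP70.2 differed by 3.31 ± 0.76 (SE, n = 2 per group; 1.67 in sow 1 and 4.95 in sow 2) and BAG3 by 2.53 ± 0.54, while other BAG3 probes differed by 1.61, 1.31, 0.54 and 0.38. SCD, measured on 1 of 2 blood arrays, differed by 3.49 ± 0.85 (1.67 in sow 1 and 5.30 in sow 2), while KLF2 differed by -2.05 ± 0.48 and CCR7 by -2.01 ± 0.50. CXCR6, a chemokine receptor of tissue T cells, was at 9.86 ± 0.43 (SD, n = 2) in colostrum and 7.13 ± 0.44 in blood, and was the only 1 of 6 tissue residency and mucosal homing genes to pass adjusted over the list alone. SLC1A5, a glutamine transporter, had the largest difference, 3.52 ± 0.66, with 1 of 2 blood arrays above background. No difference passed over all genes, and the smallest adjusted p, 0.337, was shared by several genes, SLC1A5, CXCR6 and BAG3 among them.

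The heat shock list had a median of 1.46, with 8 of 8 genes higher, but of -0.24 under 75th percentile scaling (camera adjusted p = 1.46e-05; adjusted p = 0.538 with an estimated correlation). HSP70.2, BAG3 and DNAJB1 (1.65 ± 0.48, but -0.17 under 75th percentile scaling) passed adjusted over the list alone. The naive and lymph node homing list had a median of -1.47, with 6 of 6 genes lower (camera adjusted p = 0.000153; adjusted p = 0.538 with an estimated correlation). CCR7, KLF2 and LEF1 (-1.71 ± 0.56; -0.80 in sow 1 and -2.62 in sow 2; other probes at -1.40 and -0.01) passed adjusted over the list alone. Beside this list, the CD3 chain genes CD3G and CD247 also differed, by -1.74 ± 0.79 (-0.20 in sow 1 and -3.27 in sow 2) and -1.76 ± 0.64, whereas CD3D and CD3E differed by -0.13 and -0.37. Under 75th percentile scaling all of these CD3 genes were called lower in colostrum, with CD3D at -2.06 (adjusted p = 0.0495) and CD3E at -2.29 (0.0361). The cholesterol and lipid list had a median of 0.87, or 0.67 with genes at their bound and 0.24 under 75th percentile scaling (camera adjusted p = 0.000198; adjusted p = 0.279 with an estimated correlation), with 8 of 10 genes higher, and SCD alone passed adjusted over the list. FASN differed by 2.07 ± 0.77, but its other probe that was above background in any group by -0.65, and such probes of INSIG1 and SREBF1 differed by -1.27 and -1.08. Interferon-stimulated genes had a median of 0.24 over 14 genes (camera adjusted p = 0.0441; adjusted p = 0.606 with an estimated correlation), at 0.97 in sow 1 and -0.28 in sow 2. OAS2, which senses double-stranded RNA, had the largest difference among them, 1.76 ± 0.97 with 1 of 2 blood arrays above background, and was higher in sow 1 only (3.60, against -0.08 in sow 2). FOS differed by 1.35 ± 0.54, but by -0.60 under 75th percentile scaling, and immediate early genes as a list were not called (median 0.53, adjusted p = 0.201).

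Further values with the same sign and at least 2-fold in both sows included SHAS2 (3.20 ± 0.69) and ANKFY1 (3.14 ± 0.64), higher in colostrum. P4HA1, a subunit of prolyl hydroxylase, was at least 6.41-fold higher by its tested probe (4.99 in sow 1 and 1.96 in sow 2). Its 7 other probes differed by -0.27, 0.48, 2.44, -0.12, 0.97, 0.65 and 0.06, so the probes disagree. Lower in colostrum were CAMK4, a calcium-dependent kinase (-2.84 ± 0.62), the interferon regulatory factor IRF3 (-2.74 ± 0.52), SCAP, the escort of sterol regulatory proteins (-2.78 ± 0.82), the methionine synthase MTR (-2.77 ± 0.85) and M6PR (-2.72 ± 1.09), with SCAP, MTR and M6PR measured on 1 of 2 colostrum arrays. Other probes of M6PR differed by -1.75, -0.44 and -0.17. The sows differed for SCAP (-3.75 and -1.81), MTR (-4.01 and -1.53) and M6PR (-1.51 and -3.93). The survivin gene BIRC5 was at least 3.22-fold lower, the condensin gene NCAPH2 at least 2.69-fold lower and TTC13 at least 2.32-fold lower by its tested probe, while another probe of TTC13, above background on both colostrum arrays, differed by 0.84. CD4 differed by -2.00 ± 0.65 and was lower in colostrum in both sows. CD8A differed by -0.07 ± 0.52, while a second CD8A probe, at 6.71 and 8.08 in colostrum and at the floor on both blood arrays, differed by 2.06. The CD8B probe was below background in both groups. Among markers of other cells, CSN3, measured on 1 of 2 colostrum arrays and on neither blood array, was at least 1.28-fold higher, from sow 1 alone (2.28, against -0.05 in sow 2). CD163 differed by 1.50 ± 0.82 with 1 of 2 arrays above background in each group (3.21 in sow 1 and -0.21 in sow 2; -0.33 with probes above the negative controls only). KLRK1 differed by 1.14 ± 0.51 (1.81 and 0.47) and GP9 by -1.35 ± 0.48. S100A8 was at least 2.18-fold lower, mostly from sow 2 (-0.28 in sow 1 and -2.58 in sow 2). None of these marker lists passed.

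limma called 0 genes in either direction in double positive cells, against 327 at an unadjusted p under 0.05, where 189 would be expected by chance. At least 2-fold in both sows were 98 genes higher and 185 lower, and 85 moved in opposite directions. Scaling by the 75th percentile gave 8 genes higher and 251 lower, ended the calls of the lipid (median 0.24, adjusted p = 0.435) and interferon lists (0.48, 0.562), and turned the heat shock median to -0.24 (0.774). The naive list kept its call, with a median of -3.05. Under the same scaling CD3D differed by -2.06, CD3E by -2.29, CD3G by -3.32 and CD247 by -3.28. The naive list was not set against genes of similar brightness. Without colostrum replicate 1 (adjusted p = 0.707) or blood replicate 1 (0.38) the interferon list was not called.

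Differences between colostrum and blood ran alongside in the 2 populations. Of the genes at least 2-fold higher in both sows, 37 were shared between the populations where independent lists would share 3.27, and of those at least 2-fold lower, 33 were shared against 6.72. No gene was 2-fold in both sows in opposite directions. Across the 3773 genes, which are not independent, the differences correlated at a Pearson r of 0.40 and a Spearman rho of 0.36. Both comparisons share the sows and the dye of each source, so this overlap is not evidence from independent samples. The test of the difference between the populations called 0 genes in limma, with 87 at an unadjusted p under 0.05. By chance 189 would be expected, so fewer genes than by chance reached this p. The fit had no block for the sow, although deviations of the same sow and population correlated at 0.28 and 0.22. Whether this lowered the count was not tested. With 2 samples per group, the absence of calls does not show that the populations agree. No list had a camera adjusted p below 0.409. For CD4 no size is given for this difference, since its probe was not well above background in blood CD8 single positive cells. LEF1 (2.28 ± 0.79) and HSP70.2 (-1.95 ± 1.08) had the largest such values in their lists.

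Within colostrum, double positive cells were set against CD8 single positive cells, a comparison in 1 dye. Cytotoxic effector genes were lower in double positive cells, with a median of -1.86 and 7 of 9 genes lower (camera adjusted p = 9.03e-05; adjusted p = 0.463 with an estimated correlation). The perforin gene PRF1 (-3.85 ± 0.65), NKL, the gene of NK-lysin (-3.43 ± 0.65), GZMB (-2.43 ± 0.85; -1.38 in sow 1 and -3.48 in sow 2), GZMH (-1.91 ± 0.54) and GZMA (-1.86 ± 0.63) passed adjusted over the list alone. CCL5, a chemokine of effector T cells, was at 8.62 ± 0.35 (SD, n = 2) in double positive and 12.49 ± 0.11 in CD8 single positive cells and had the smallest adjusted p over all genes, 0.0522. The NK and gamma delta T cell list had a median of -2.01 (camera adjusted p = 0.00392, and 0.463 with an estimated correlation). Only 3 of the 10 genes of this list were measured, KLRK1, FCER1G and KIT, so the shift does not identify those cells. KLRK1 differed by -2.01 ± 0.51 and FCER1G by -2.64 ± 0.72. PRF1, GZMA, GZMB and FCER1G were measured on 1 of 2 double positive arrays. The helper cell genes CD40LG (2.16 ± 0.58) and ICOS (1.78 ± 0.50) and the mitotic kinase gene AURKB (at least 1.55-fold) were higher in double positive cells and passed adjusted over their lists alone.

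Immediate early genes had a median of -0.72 over 8 genes (camera adjusted p = 0.0387; adjusted p = 0.608 with an estimated correlation), and EGR2 was at least 2.86-fold lower in double positive cells. Inflammatory cytokines and chemokines had a median of -0.77 over 10 genes, or -0.05 with genes at their bound (camera adjusted p = 0.0387; adjusted p = 0.463 with an estimated correlation). CCL4 differed by -2.30 ± 0.60 and CCL3L1 was at least 2.10-fold lower. The sort genes as a list had a median of -0.61 (camera adjusted p = 0.0387; adjusted p = 0.696 with an estimated correlation). CD8B was at least 6.89-fold lower, CD8A differed by -1.01 ± 0.52 (0.11 with the mean of its probes), CD4 by 0.92 ± 0.65 (1.78 in sow 1 and 0.06 in sow 2), CD3G by -1.46 ± 0.79 (-0.65 and -2.26), CD247 by -0.61 ± 0.64, CD3E by -0.35 ± 0.49 and CD3D by -0.29 ± 0.51. CSN1S1 was at least 5.43-fold lower in double positive cells by its tested probe (-2.01 in sow 1 and -5.92 in sow 2), MRC1 at least 1.30-fold higher and CXCR2 at least 1.02-fold lower. ITGA2B, measured on 1 of 2 CD8 single positive arrays, differed by 1.19 ± 0.59 (2.13 in sow 1 and 0.25 in sow 2).

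limma called 0 genes within colostrum, with 266 at an unadjusted p under 0.05, where 189 would be expected by chance. With the pair as a random block, CCL5 was called lower (adjusted p = 0.0463), and normexp called CCL5 (0.00212), CD8B (0.0344) and PRF1 (0.0344). A stricter filter called CCL5 (0.0432), and probes above the negative controls alone gave CCL5 (0.0153) and CD8B (0.0436). With the sow as a block, the sort gene (adjusted p = 0.0573), inflammatory (0.0694) and immediate early lists (0.0536) were not called. The inflammatory list was also lost under 75th percentile scaling (0.395) and cyclic loess (0.309), and the NK and gamma delta list without a filter on dim probes (0.056). Without CD8 single positive replicate 1 the NK and gamma delta (0.204), sort gene (0.204) and inflammatory lists (0.111) were not called, without CD8 single positive replicate 2 the inflammatory (0.22), immediate early (0.34) and sort gene lists (0.0678), without double positive replicate 1 the inflammatory (0.211) and immediate early lists (0.496), and without double positive replicate 2 the sort gene list (0.387). That list was also lost without either blood double positive replicate (0.0507).

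Within blood, cytotoxic effector genes were also lower in double positive cells. The list had a median of -1.58, with 8 of 9 genes lower in double positive cells (camera adjusted p = 6.35e-06; adjusted p = 0.411 with an estimated correlation). PRF1 (-4.05 ± 0.65), GZMB (-3.81 ± 0.85), NKL (-3.35 ± 0.65), GZMM (-1.85 ± 0.52) and GZMH (-1.58 ± 0.54) passed adjusted over the list alone. PRF1, GZMB and GZMM were measured on 1 of 2 double positive arrays. GZMA was below background in both populations of blood. CCL5 was at 8.50 ± 0.34 (SD, n = 2) in double positive and 12.11 ± 0.01 in CD8 single positive cells, with the smallest adjusted p over all genes, 0.0906. CD40LG, the ligand through which helper T cells act on CD40, was at 11.51 ± 0.66 in double positive and 8.90 ± 0.55 in CD8 single positive cells, a difference of 2.61 ± 0.58.

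The NK and gamma delta T cell list, with the same 3 of 10 genes measured, had a median of -2.47 in blood. With genes at their bound the median was -0.93. The camera adjusted p was 0.00164, and 0.411 with an estimated correlation. KLRK1 differed by -2.47 ± 0.51 and KIT was at least 1.91-fold lower. Inflammatory cytokines and chemokines had a median of -0.59, or -0.05 with genes at their bound (camera adjusted p = 0.0158; adjusted p = 0.411 with an estimated correlation), and CCL4 differed by -2.72 ± 0.60. Of the sort genes, CD4, CD8B and CD8A (-1.66 ± 0.52; -0.89 in sow 1 and -2.42 in sow 2) passed adjusted over the list alone, with CD8B at least 2.68-fold lower. CD3D differed by -0.26 ± 0.51, CD3E by 0.04 ± 0.49, CD3G by -0.10 ± 0.79 and CD247 by 0.70 ± 0.64. Among markers of other cells, LYZ, not well above background in double positive cells, was at least 1.62-fold lower in them (-1.64 in sow 1 and -0.55 in sow 2). PIGR, measured on 1 of 2 CD8 single positive arrays, was at least 1.17-fold lower and S100A8, also measured on 1 of 2 of them, differed by 0.63 ± 0.82. limma called 0 genes within blood, with 210 at an unadjusted p under 0.05, where 189 would be expected by chance. Cyclic loess normalization gave 7 genes higher and 7 lower in limma, each at an adjusted p of 0.044. CD4, CD8B and CCL5 were among them, but so were FGG (3.31), SLC45A2 (3.67), VSIG4 (-4.48) and PIGR (-3.61), which is on a list of other cells. In the blood channels 17.7% to 23.4% of the probes lay at or below 0 before this setting, and whether dim probes gave these calls was not tested. Normexp called CCL5 (0.0046) and PRF1 (0.0259). Probes above the negative controls alone gave CCL5 (0.0254). The inflammatory list was lost under 75th percentile scaling (0.249) and cyclic loess (0.63), and without CD8 single positive replicate 2 (adjusted p = 0.516) or double positive replicate 2 of blood (0.0665) it was not called.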

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

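Of the 33325 probes without a gene name, which the comparisons above do not use, 3871 exceeded the 95th percentile of the negative-control spots in all 8 samples, next to 2464 of the named probes. Of these unnamed probes, 71 were at least 2-fold higher in colostrum in both sows and both populations, and 13 were at least 2-fold lower. The same counts were 41 and 35 among the named probes. They are reported as a signal outside the genes tested, and the transcripts they measure are not analysed here.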

How the results depend on the processing

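The floor of 1 unit, the restriction to probes above the negative controls and, for the lists, normexp were chosen after seeing the data; the genes put through these settings are those the naming rule picks and those the text names. This set had been narrowed after a wider run was seen and was then widened again. No count of genes passed in limma, so every alternative that differs adds calls: 123 of 148 alternative counts stayed within 1.5 times, which for a count of 0 means at 0. Of 153 alternative list tests, 109 stayed called with the same direction. None of the values of named genes was a call in the main fit: 4135 kept their sign and gained no call, 43 gained a call and 22 turned sign. These counts of genes and values therefore do not measure how firm a call is. The calls of the naive, heat shock, lipid and cytotoxic lists, and of NK and gamma delta genes in blood, held without any 1 of the 8 samples. An estimated correlation ended all 17 list calls, but it also leaves camera only the 4 residual degrees of freedom. The lipid list had an estimated correlation of -0.00577, below the preset 0.01, and still lost its calls. The lost calls therefore do not show that the genes of a list are correlated. Scaling by the 75th percentile ended 9 list calls. The 99th percentile is 22.5 to 29.9 times the 75th in colostrum channels and 82.8 to 110 times in blood channels. In colostrum channels the 75th percentile was 199 to 216 units, where the 95th percentile of the negative controls was 163 to 185. In blood channels it was 85 to 99 units, against 49.8 to 78.2. This scaling therefore rests on the level of dim probes, which the bright probes did not follow alike in the 2 dyes. The cause of the change and which scaling is right were not tested. Camera takes no random block, so the lists were not run with the pair.

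Scaling by the 75th percentile gave 2 genes lower in CD8 single positive cells and 8 higher and 251 lower in double positive cells. List adjusted p-values under it were 0.58 for type 1, 0.782 for immediate early (reversed), 0.494 for heat shock and 0.494 for lipid genes in CD8 single positive cells, and 0.562 for interferon-stimulated, 0.774 for heat shock (reversed) and 0.435 for lipid genes in double positive cells. For inflammatory genes it was 0.395 within colostrum and 0.249 within blood. Genes that turned were ENTPD1 (-2.202), DNAJB1 (-0.09417), SLC3A2 (-0.06024), MCL1 (-0.1454) and PRDX6 (-0.1606) in CD8 single positive cells, and DNAJB1 (-0.1733), ATF4 (-0.1794), FOS (-0.5953), NFKB1 (-0.2117), MCL1 (-0.4139), SAT1 (-0.8425) and PRDX6 (-0.5696) in double positive cells. In the difference between the populations ENTPD1 turned to 2.632, and with cyclic loess to 2.391.

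Cyclic loess gave 7 genes higher and 7 lower between the populations in blood, ENTPD1 at -3.05 in CD8 single positive cells, and list adjusted p-values of 0.0545 for type 1, 0.0507 for the sort genes, and 0.309 within colostrum and 0.63 within blood for inflammatory genes. The deposited matrix values gave 0.217 within colostrum and 0.217 within blood for inflammatory genes. Normexp gave 1 gene higher and 2 lower in CD8 single positive cells, 3 lower within colostrum, 2 lower within blood, and 0.0535 for type 1. Without a filter the interferon list was at 0.187 and NK and gamma delta genes in colostrum at 0.056. A stricter filter gave 1 gene lower within colostrum. Probes above the negative controls alone gave 2 lower within colostrum and 1 within blood, 0.0686 for the sort genes, 0.0686 for immediate early genes, both within colostrum, and CD163 at -0.3293 in double positive cells. A floor of 1 turned P4HA1 to -0.1203 in double positive cells and BID to -0.4559 within blood, where the deposited matrix gave BID at -0.4516. In these 3 cases the setting made another probe the brightest, as it did for ENTPD1 under 75th percentile scaling and cyclic loess, for SLC3A2 and for CD163, so a disagreement between probes is mixed into these turns.

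With the sow as a replicate block the lists within colostrum were at 0.0573 for the sort genes, 0.0694 for inflammatory and 0.0536 for immediate early genes. With the pair of sow and population as a block (correlation 0.24), 1 gene was higher and 1 lower in CD8 single positive cells and 1 lower within colostrum. The pairing changed no other call. The mean of the probes of a gene gave 0.285 for the sort genes, 0.0757 for inflammatory and 0.065 for immediate early genes within colostrum, 0.185 for inflammatory genes within blood, ENTPD1 at -0.2467 in CD8 single positive cells and CD8A at 0.1119 within colostrum.

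At least 2-fold in both sows with no p, higher and lower, were 126 and 137 genes in CD8 single positive cells, 98 and 185 in double positive cells, 89 and 172 for the difference between these, 99 and 138 within colostrum and 102 and 81 within blood. With an estimated correlation the adjusted p in CD8 single positive cells was 0.283 for naive, 0.321 for type 1, 0.321 for immediate early, 0.321 for heat shock and 0.283 for lipid genes. In double positive cells it was 0.538 for naive, 0.606 for interferon-stimulated, 0.538 for heat shock and 0.279 for lipid genes. Within colostrum it was 0.696 for the sort genes, 0.463 for cytotoxic, 0.463 for inflammatory, 0.608 for immediate early and 0.463 for NK and gamma delta genes, and within blood 0.411 for cytotoxic, 0.411 for inflammatory and 0.411 for NK and gamma delta genes.

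Leaving out samples in turn gave 0 to 1 genes higher in CD8 single positive cells, the 1 without either colostrum double positive replicate, and 0 otherwise. In the difference between the populations SLA-DRA ranged from -2.232 without colostrum double positive replicate 1 to 0.1431 without replicate 2. List adjusted p-values ranged from 0.0178 to 0.335 for type 1 and 0.00575 to 0.114 for immediate early genes in CD8 single positive cells, and from 0.00682 to 0.707 for interferon-stimulated genes in double positive cells. Within colostrum they ranged from 0.00714 to 0.387 for the sort genes, 0.0381 to 0.22 for inflammatory, 0.0171 to 0.496 for immediate early and 0.000259 to 0.204 for NK and gamma delta genes, and within blood from 0.00139 to 0.516 for inflammatory genes.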

Other observations

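The genes of this paragraph were chosen after their values were seen, no list or test covers them as groups, and the tests of the dye on each gene, of the share of T cells, of mammary epithelial RNA, of a bias of the chosen probes and of a dye difference that grows with brightness were chosen or changed after their results were seen. ATF4, a transcription factor of the integrated stress response, had higher values in colostrum in both sows, by 1.81 ± 0.57 (SE, n = 2 per group) in CD8 single positive cells and 1.63 ± 0.57 in double positive cells, and its target DDIT3 by 2.14 ± 0.62 and 1.50 ± 0.62. The amino acid transporter genes SLC3A2 (1.50 ± 0.56 and 1.67 ± 0.56) and SLC1A5 (2.33 ± 0.66 and 3.52 ± 0.66) were higher in both, as were SAT1, which breaks down polyamines (1.99 ± 0.48 and 1.30 ± 0.48), and the peroxiredoxin gene PRDX6 (1.47 ± 0.48 and 1.35 ± 0.48). Other probes of SLC1A5 differed by 1.98 and 0.09 in CD8 single positive cells, and those of PRDX6 ranged from -0.35 to 1.04 in double positive cells. The selectin ligand gene SELPLG differed by -1.54 ± 0.56 and -1.98 ± 0.56 (measured on 1 of 2 colostrum double positive arrays), ICAM2 by -1.59 ± 0.53 and -1.52 ± 0.53, and the filamin gene FLNA by -1.51 ± 0.49 and -1.59 ± 0.49. None of these passed limma's test in the main analysis, the lowest adjusted p being 0.337, for SLC1A5 in double positive cells. Scaling by the 75th percentile turned SLC3A2 in CD8 single positive cells to -0.06 and PRDX6 there to -0.16, and in double positive cells ATF4 to -0.18, SAT1 to -0.84 and PRDX6 to -0.57. Under it limma called 8 genes higher and 251 lower in double positive cells. Among them were SLC1A5 (3.13, adjusted p = 0.0441), SELPLG (-2.82, 0.0302), ICAM2 (-2.90, 0.0283) and FLNA (-2.91, 0.0283).

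CSN1S1, a casein gene, was at 7.36 in sow 1 and 11.38 in sow 2 in colostrum CD8 single positive cells and at 5.58 and 8.60 in the blood CD8 single positive cells of the same sows, while all 4 double positive samples lay between 5.34 and 6.15. This is 1 probe of CSN1S1: only 1 of its other probes was above background on both arrays of any group, and it went the other way, at 5.34 and 6.16 in colostrum and 7.13 and 7.57 in blood CD8 single positive cells, a difference of -1.60. A second CD4 probe read 7.81 and 6.90 in colostrum double positive cells and 8.68 and 8.77 in blood double positive cells, a difference of -1.37, in the direction of the brighter probe.

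At camera's preset correlation heat shock genes were called higher in colostrum in both populations and immediate early genes in CD8 single positive cells, but with an estimated correlation none of these calls stood (adjusted p = 0.321 and 0.538 for heat shock and 0.321 for immediate early genes). Immediate early genes were not called in double positive cells (0.201), and neither list was called for the difference between the populations (0.409 for both). The 16 genes together were not tested as a list. The higher level of the negative controls in the Alexa Fluor 3 channel stays open. With normexp background correction the median of the 16 kept at least 0.937 of its size in both populations. That could not decide it, since normexp leaves the order of probes within a channel unchanged. The quantile normalization that followed uses only this order. A dye difference that grows with brightness stays open: the 16 genes kept at least 0.994 of their median against genes of like brightness, but that comparison repeats what quantile normalization does, and under 75th percentile scaling their medians were -0.138 and -0.645. A bias of the chosen probes stays open, since 44 other probes of 12 of these genes kept 0.717 of the median in CD8 single positive but 0.345 in double positive cells. Of the 44 probes, 24 belong to 2 genes. The lowest share without any single gene was 0.672 (without DNAJB1) and 0.232 (without HSP90AA1). Gene by gene, 9 of 12 kept at least 0.5 in CD8 single positive cells, 6 in double positive cells and 4 in both. A dye effect on single genes cannot be told apart from the source of the cells, with 0 arrays of colostrum in Alexa Fluor 5, and the cells' source and their handling before lysis stay open as untested.

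Naive and lymph node homing genes had lower values in colostrum, a call made in both populations at the preset correlation and in neither with an estimated one (adjusted p = 0.283 and 0.538). A lower share of T cells in the sort would lower the CD3 chain genes alike. In CD8 single positive cells the median of these lay above that of the list by 1.56 (SE 0.57), which met the rule set for arguing against it. In double positive cells the distance of 0.421 (SE 0.48) did not, and that test's rule was tightened after its value was seen. Both SEs are the spread over genes for a difference of means, not the limma SE and not a spread over sows. The values show that the CD3 chain genes fell less than the list on average in CD8 single positive cells. With 2 sows the explanation stays open in both populations. A bias of the chosen probes stays open, with 4 other probes of 3 genes keeping at least 0.431 of the median. A smaller share of naive cells in colostrum is a candidate that no value here tests apart from the dye.

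Cholesterol and lipid synthesis genes had higher values in colostrum in the main analysis, but the calls were lost with an estimated correlation (adjusted p = 0.283 in CD8 single positive and 0.279 in double positive cells), and 75th percentile scaling took the medians from 0.667 to 0.059 and from 0.874 to 0.242. Mammary epithelial cells, which the CD3 gate should remove, make the same transcripts. In CD8 single positive cells 3 of 5 milk protein genes, CSN1S1, CSN2 and CSN3, had a probe above background on both colostrum arrays and at least 2-fold higher than in blood, which met the first wording of the test, but 2 of 5 had a probe as far the other way, and the median of the 5 tested probes was -0.161, so RNA of those cells cannot be told apart. In double positive cells this held for 1 of 5, CSN1S2 (1.84), with none the other way. The 5 genes were read by 48 probes, and 31.1% to 34.7% of all probes were above background in a colostrum channel. A probe of EPCAM was also above background on both colostrum arrays (1.295), at 7.20 and 7.11 against thresholds of 6.89 and 6.96. It was the only such one among many other EPCAM probes. Single probes found among so many are weak evidence, and RNA of those cells stays open there too. A bias of the chosen probes stays open: 18 other probes of 7 genes kept at least 0.601 of the median in both populations, as the prediction asked, but 11 of them belong to SCD and LPIN1, and without SCD the share was 0.312 and 0.272. Gene by gene, 2 of 7 kept at least 0.5 in each population and 0 in both, with other probes of FASN, INSIG1, SREBF1 and SQLE near 0 or lower in colostrum in at least 1 population. The dye and the source of the cells stay open.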
